A study of Mus musculus with 2 samples.

How the data were processed

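Gene expression was measured with 10x Genomics droplet sequencing in mouse embryos of embryonic day 7.0, the time of gastrulation. The Hand1 CKO library came from embryos of the genotype Hand1 F/F; Mesp1 cre, in which Cre recombinase under Mesp1 is meant to delete the floxed Hand1 gene in early mesoderm. The Ctrl library came from embryos carrying Hand1 F/F or Hand1 F/+, with no Cre named. Each group has 1 library of pooled embryos of the strain C57/B6J, and the number of embryos is not given in the sources used here. Per the labels' protocols, Reichert's membrane and the ectoplacental cone were removed, embryos were genotyped, and tissue was digested to single cells with TrypLE. The labels name the molecule as nuclear RNA although the protocol describes whole single cells, so it stays open whether cells or nuclei were sequenced.

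The deposited matrix holds raw UMI counts (unique molecular identifiers, a tag for each captured transcript) for 32285 genes and 16519 barcodes, written by Cell Ranger 7.0.1 per the file headers and per the submitters' processing notes, which name mm10 as the genome build. Whether reads on the opposite strand or in introns were counted is not given in the sources used here, so values of genes that overlap another gene are uncertain to that extent. Among the named genes this holds for Rpgrip1 with Supt16, Mest with Copg2, Dok4 with Polr2c, Fabp3 with Zcchc17, Smarcd3 with Chpf2, Tagln with Pcsk7, Cald1 with Npn2, Tpi1 with Spsb2, Cdc20 with Elovl1, Nefl with Nefm, Col4a1 with Col4a2 and Xist with Tsix. It also holds for others with another gene annotated on the other strand, among them Hoxb6, Plxna4, Lmo2, Ecscr and Cdkn1a. The authors also deposited an annotation of 13948 cells with the library and 1 of 12 cell classes for each, without stating how the classes were made. The annotation names the libraries KO and WT. KO was matched to Hand1 CKO and WT to Ctrl because these are the only mutant and control samples of the series.

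Cells were joined to the matrix by barcode. The barcodes of 14 cells occur in both libraries while the matrix holds 1 column for each, so these 28 annotated cells were left out and 13920 were used. Another 2585 barcodes have no annotation and were not used. They held 3.86% of all UMIs, with a median of 1175 UMIs and 678 genes, and 1878 of them lay under the smallest gene number among annotated cells, 820. The annotated cells had at most 9.98% mitochondrial UMIs, and 313 of the barcodes without annotation lay above that. No further filter on cells was set. A symbol shared by several features (78 features) was kept apart by its Ensembl identifier.

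Classes were used as deposited. Mesoderm was defined from the class names alone as Nascent mesoderm, Mixed mesoderm, Blood progenitors and Mesenchyme, and Epiblast served as the largest class outside the Mesp1 lineage. UMIs were summed over the cells of a class in each library, scaled to CPM (UMIs per 1e+06 UMIs of the class), and compared as log2((CPM in Hand1 CKO + 1)/(CPM in Ctrl + 1)), called log2 ratio here. This scale understates differences of low genes. Genes entered with a mean of 10 CPM or more and 50 or more UMIs over both libraries, and classes with 100 or more cells in each library. With 1 library per group no test was possible, and there are no p-values, standard errors or counts of changed genes. Intervals are exact 95% intervals, Poisson for CPM and binomial (Clopper-Pearson) for shares of cells. The interval of a log2 ratio comes from the binomial interval of the Hand1 CKO share of the UMIs, without the added 1 CPM, so the log2 ratio of a low gene can lie just outside it. These intervals cover counting error only, not differences between embryos, litters or library preparations. Those of CPM and log2 ratios also leave out the spread between cells.

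To compare shares of cells with a UMI, each cell was thinned to 5000 UMIs. This left out 2286 shallower cells of Hand1 CKO and 459 of Ctrl. For 24 gene lists, the median log2 ratio of members that passed the filter was set against 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. A list is said to stand apart where its median lay below the percentile 2.5 or above 97.5. The lists were epiblast and ectoderm, primitive streak, nascent mesoderm, extraembryonic mesoderm, lateral plate and cardiac mesoderm, haemato-endothelial progenitors, primitive erythroid, paraxial and presomitic mesoderm, allantois and posterior Hox, axial mesoderm and node, definitive endoderm, visceral endoderm, parietal endoderm, extraembryonic ectoderm and trophoblast, primordial germ cells, BMP pathway and targets, epithelial-mesenchymal transition, smooth muscle and actin cytoskeleton, glycolysis and hypoxia, p53 targets and apoptosis, dissociation stress, S phase, G2/M phase and sex-linked genes. Some genes stand in more than 1 list.

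The groups, gene lists, measures, most alternatives and the rule for named genes were set before the data were examined. The rule names Hand1, Mesp1 and the sex-linked genes, then the 10 highest and 10 lowest log2 ratios in all mesoderm. It adds the 3 highest and 3 lowest in each mesoderm class with 100 or more cells in each library, the 5 highest and 5 lowest in Epiblast, and from each list up to 4 members with the largest absolute log2 ratio in mesoderm. Apart from the fixed and list genes, it leaves out mitochondrial, ribosomal protein and sex-linked genes and gene models without a name. Coordinates of the 108 named genes, all found by identifier, come from the GENCODE vM21 annotation of GRCm38, the assembly known as mm10.

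Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3. Scrublet, as built into Scanpy 1.11.5, was run within each library with an expected doublet rate of 6%. Its threshold called 0 of 8406 cells in Hand1 CKO and 2 of 5514 in Ctrl, 0.036%, so its calls were not used and no cells were removed as doublets. Whether doublets were removed before deposit is not given in the sources used here. An own clustering used 2000 variable genes, 30 principal components centred per library, 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1. It gave 17 clusters, of which 7 had no name under markers fixed beforehand. The unnamed clusters held 45.7% of Hand1 CKO cells and 27.3% of Ctrl cells. Counts were also simulated as independent Poisson draws per gene from a pooled profile, which is the model that the intervals assume. These runs check the calculation, not the spread between cells or genes that change together. On such counts for 7295 genes in mesoderm, the gene intervals held the true ratio for 94.9% of unchanged genes and 96% of genes changed by 1 or 2 log2 units. A simulated list raised on purpose reached the percentile 100, and 5 of 100 unchanged lists fell outside the middle 95% in mesoderm, 7 of 100 in Epiblast and 9 of 100 in Blood progenitors.

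The alternatives were a pseudocount of 0.1 or 5 CPM, median-of-ratios size factors, and totals without mitochondrial and ribosomal protein genes. Others were no filter beyond 1 UMI, a mean of 50 CPM, thinned cells, equal weights for mesoderm classes, shares without cells under 2000 UMIs, shares without extraembryonic endoderm and ectoderm, and own clusters in place of the classes. Further ones were chosen after seeing the data, namely leaving out cells under 10000 UMIs, using only cells of 20000 to 40000 UMIs, leaving out Mesenchyme, and leaving out the 6% of cells with the highest doublet scores.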

Results

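The transcriptomes of gastrulating mouse embryos were compared at embryonic day 7.0 between a library with conditional deletion of Hand1 in the Mesp1 lineage (Hand1 CKO) and a control library (Ctrl). Hand1 encodes a basic helix-loop-helix transcription factor of the extraembryonic mesoderm and the heart, and Mesp1 encodes one that marks the earliest mesoderm. The Hand1 CKO library gave 8406 cells with 154981751 UMIs, and the Ctrl library gave 5514 cells with 160158313 UMIs. The cells of Hand1 CKO were shallower, with a median of 11837 UMIs and 3156.5 genes per cell against 27280 UMIs and 5027.5 genes in Ctrl. Cells under 5000 UMIs made up 27.2% of Hand1 CKO and 8.32% of Ctrl. Median mitochondrial shares were 1.29% and 1.49%, and ribosomal protein genes took a median of 28.4% of UMIs in each. Each group had 1 library without replicates, so every value below describes these 2 libraries.

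The first question was whether Hand1 itself was lower in the mesoderm, where Cre should act. Hand1 (ENSMUSG00000037335, a gene of 2 exons on the minus strand of chromosome 11, 57828705 to 57832818 in mm10) was at 51.7 CPM (95% interval 50.1 to 53.5) in the mesoderm of Hand1 CKO and at 120 CPM (118 to 123) in that of Ctrl. The log2 ratio was -1.20 (-1.28 to -1.16), and the level in Hand1 CKO was 43.0% of the control level. Mixed mesoderm held 115 CPM against 287 CPM, Nascent mesoderm 19.8 CPM against 35.3 CPM, Blood progenitors 5.18 CPM against 19.0 CPM and Mesenchyme 209 CPM against 363 CPM. The own cluster that held the largest part of Mixed mesoderm was cluster 12 in Hand1 CKO (41.2%) and cluster 4 in Ctrl (74.2%). In Epiblast, outside the Mesp1 lineage, Hand1 was at 3.87 CPM against 3.78 CPM, in ExE ectoderm at 44.3 CPM against 38.9 CPM and in ExE endoderm at 18.9 CPM against 15.3 CPM. The small Visceral endoderm class differed, with 33.0 CPM (24 UMIs in 22 cells) against 0 UMIs in 43 cells, which allows up to 3.32 CPM. The related gene Hand2 went the same way in that class (17.9 CPM against 0 UMIs).

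At a thinned depth of 5000 UMIs per cell, 43.5% of Mixed mesoderm cells in Hand1 CKO (40.1% to 47.0%) and 70.7% in Ctrl (66.0% to 75.1%) had a Hand1 UMI. Without thinning, these shares were 71.1% and 96.8%, at median depths of 16788 and 30530 UMIs. In Epiblast, which should lack Hand1, the thinned shares were 1.16% and 1.56%, and the unthinned ones were 4.87% and 6.79% at medians of 14059 and 27111 UMIs. The sources used here do not say which part of Hand1 is floxed. Droplet reads gather at the end of the transcript and need not lie in the deleted part, so the remaining UMIs do not measure how many cells kept the gene.

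**Figure D1:**
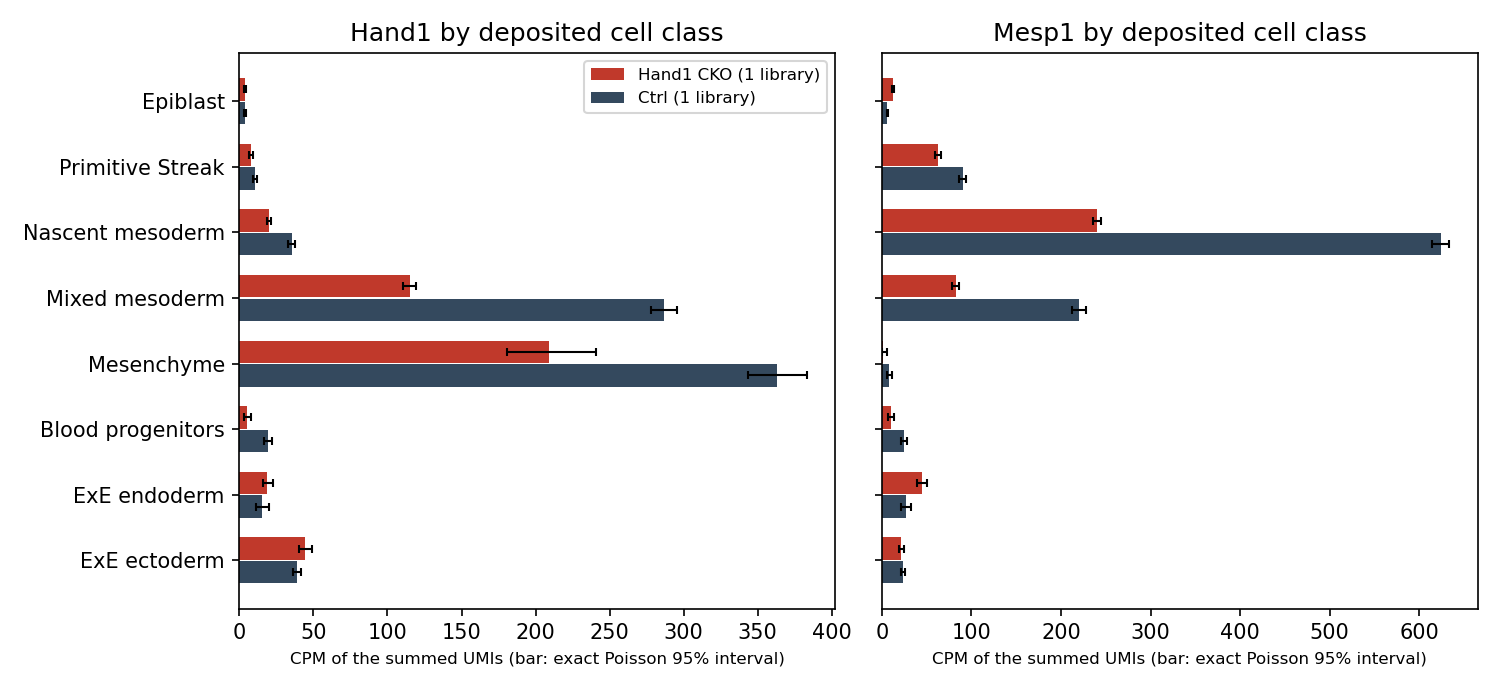
Hand1 (left) and Mesp1 (right) in CPM of the summed UMIs of each deposited class, for the Hand1 CKO library (red) and the Ctrl library (dark), with exact Poisson 95% intervals that cover counting error only. Hand1 was at 115 CPM against 287 CPM in Mixed mesoderm, and Mesp1 was at 240.3 CPM against 624 CPM in Nascent mesoderm.

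Mesp1 (ENSMUSG00000030544, chromosome 7, 79792241 to 79793788, minus strand, 2 exons) was also lower in the mesoderm of Hand1 CKO, at 172 CPM against 378 CPM, a log2 ratio of -1.13 (-1.17 to -1.11). In Nascent mesoderm it was at 240.3 CPM against 624 CPM (log2 ratio -1.37), and in Mixed mesoderm at 82.3 CPM against 220.4 CPM (-1.41). In the Primitive Streak class, whose largest own cluster was the shallow cluster 1 in Hand1 CKO (34.8%) and cluster 0 in Ctrl (31.9%), the log2 ratio was -0.52. In Epiblast Mesp1 was low but higher in Hand1 CKO, with a log2 ratio of 0.93 and 5.86 CPM in Ctrl.

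The next comparison asked how the cells were divided among the classes. Mesoderm made up 36.1% of Hand1 CKO cells (35.1% to 37.2%) and 29.6% of Ctrl cells (28.4% to 30.9%). Nascent mesoderm held 21.7% against 15.3%, and Mixed mesoderm 11.7% against 7.87%. Blood progenitors were fewer in Hand1 CKO, with 210 of 8406 cells (95% interval 2.18% to 2.85%) against 271 of 5514 cells (4.36% to 5.52%). Mesenchyme, led in Ctrl by Acta2, Tdo2, Tnnt2 and Pitx1, held 0.26% (22 cells) against 1.51% (83 cells). Within the mesoderm alone, Blood progenitors were 6.92% against 16.6% and Mesenchyme 0.72% against 5.08%.

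Among other classes, the Primitive Streak held 24.9% of Hand1 CKO cells against 16.9% in Ctrl, Epiblast 24.7% against 32.3% and ExE ectoderm 6.07% against 11.9%. ExE endoderm was at 4.08% against 4.41%, Anterior Primitive Streak at 2.34% against 2.38%, PGC at 1.02% against 1.16%, Def. endoderm at 0.56% in both and Visceral endoderm at 0.26% against 0.78%. The deposited name Def. endoderm stands against its leading genes, Noto, Foxj1, Tekt1 and Pifo, which are genes of the node and of cilia. Anterior Primitive Streak was led by Cer1, Sox17, Foxa2 and Gsc in both libraries, and of the lists it was nearest to definitive endoderm. Primitive Streak cells were shallow in Hand1 CKO, with a median of 6101 UMIs against 24873.5 in Ctrl. Dissection and this depth gap can set such shares. Among cells of 20000 to 40000 UMIs only, the Primitive Streak held 17.5% against 18.2%, so this difference was not kept at matched depth. Blood progenitors held 4.22% against 4.46% in those cells but 3.23% against 5.10% without cells under 10000 UMIs, so it stays open how far depth sets their share. Mesenchyme in cells of 20000 to 40000 UMIs held 0.55% against 1.40%, Anterior Primitive Streak 3.76% against 2.48%, PGC 1.74% against 1.12%, Def. endoderm 0.55% against 0.32% and ExE endoderm 3.03% against 2.59%, each higher in Hand1 CKO apart from Mesenchyme. With own clusters in place of the deposited classes, the mesoderm share was 26.8% in Hand1 CKO and 28.4% in Ctrl, the opposite order, with more cells of Hand1 CKO left unnamed.

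**Figure D2:**
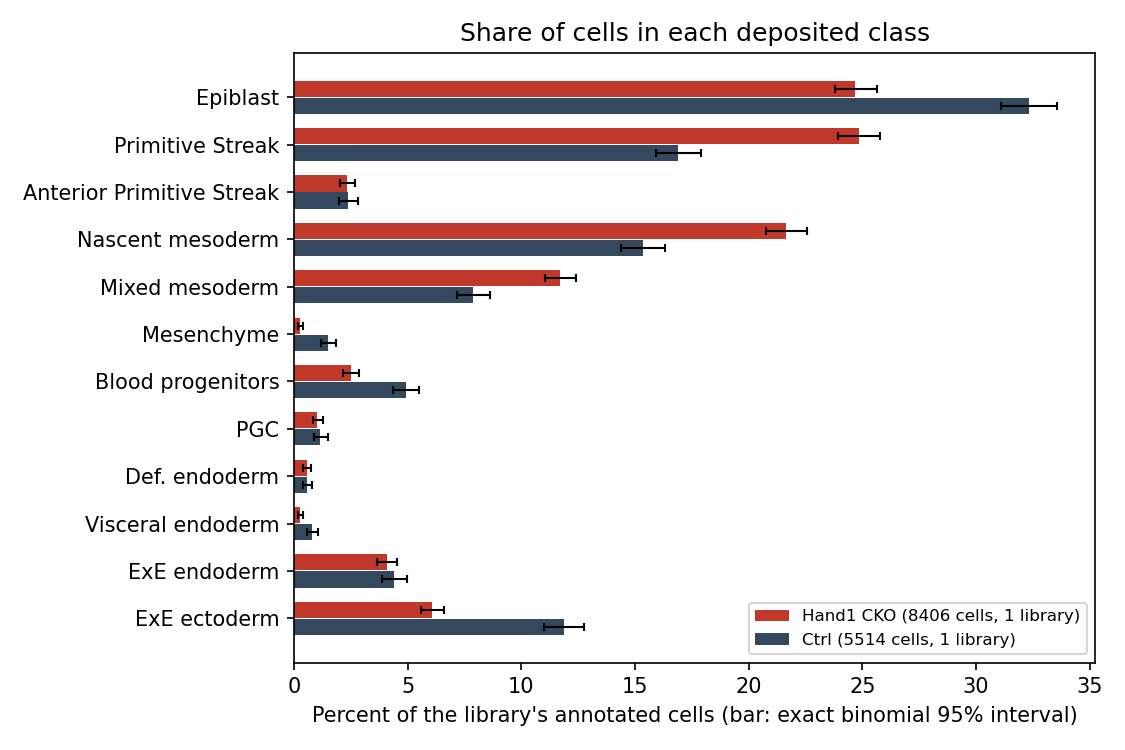
Percent of annotated cells in each deposited class, for Hand1 CKO (red, 8406 cells) and Ctrl (dark, 5514 cells), with exact binomial 95% intervals that cover counting error only. Mesenchyme takes a smaller share in Hand1 CKO (0.26%) than in Ctrl (1.51%), and the Primitive Streak a larger one (24.9% against 16.9%), the latter not among cells of 20000 to 40000 UMIs.

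Over all mesoderm cells, 7315 genes passed the filter, and 95% of their log2 ratios lay between -0.43 and 0.40. The lowest log2 ratio was that of Spin2c on chromosome X (-1.87, 30.3 CPM against 114 CPM). It was followed by Acta2 (-1.86), the smooth muscle actin, the imprinted genes Dlk1 (-1.81) and Mest (-1.77), then Dok4 (-1.59), Stard8 (-1.58), Pmp22 (-1.47), Plac1 (-1.41), the embryonic globin Hbb-bh1 (-1.26) and Hand1 itself. Acta2 was at -0.55 without the Mesenchyme class. With equal weights for the 3 mesoderm classes of 100 or more cells, Hbb-bh1 was at 1.06, Spin2c at -1.22, Dlk1 at -1.14, Stard8 at -0.94 and Pmp22 at -0.82. Dok4 overlaps Polr2c and Mest overlaps Copg2 on the other strand, so part of their UMIs is uncertain.

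The highest log2 ratio was that of Rpgrip1 on chromosome 14 (2.03, 133 CPM against 31.8 CPM), which overlaps Supt16 on the other strand. Trh (1.63) and Spink1 (1.63), which encode a hypothalamic hormone precursor and a trypsin inhibitor, came next. The cell cycle inhibitor Cdkn1a (1.62), the X-linked homeobox gene Rhox5 (1.58), Gap43 (1.52), the metallothioneins Mt2 (1.48) and Mt1 (1.38), Amt (1.46) and Fabp3 (1.45) completed the set. In cells of 20000 to 40000 UMIs only, Trh was at 1.58, Cdkn1a at 1.54 and Rhox5 at 1.07. In those cells Rpgrip1 was at 1.26, Mt1 at 0.73, Fabp3 at 0.71, Mt2 at 0.68, Spink1 at 0.60 and Amt at 0.43. Rpgrip1 was also among the leading genes of the unnamed own clusters 1, 8 and 15. Cluster 1 held 1526 cells of Hand1 CKO and 129 of Ctrl, cluster 8 held 634 and 141, and cluster 15 held 78 and 118.

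Genes of the blood and endothelial lineage were lower in the mesoderm of Hand1 CKO as a whole. All 9 measured members of the haemato-endothelial list had log2 ratios below 0, with a median of -0.79, lower than the matched random lists, among them the transcription factors Fli1 (-1.09), Lmo2 (-1.07) and Tal1 (-0.92) and the receptor Kdr (-0.83). Within Blood progenitors, 6 of 15 members were above 0 and the median was -0.06. With equal weights for the mesoderm classes the median in mesoderm was -0.07, with Fli1 at -0.13, Lmo2 at -0.02 and Tal1 at -0.07. The median in cells of 20000 to 40000 UMIs was -0.42, with Tal1 at -0.42. Of the primitive erythroid list only Hbb-bh1 was measured over all mesoderm, and in Blood progenitors 4 members had a median of 0.02.

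Genes of the nascent mesoderm were lower too, with 2 of 11 members above 0 and a median of -0.36. Fgf3 (-1.16), Mesp1 (-1.13), Lhx1 (-0.69) and the Nodal inhibitor Lefty2 (-0.67) were the lowest. Lefty2 was at 0.25 with equal weights for the classes. In Nascent mesoderm alone 1 of 11 members was above 0 and the median was -0.62. The list of paraxial and presomitic mesoderm had a median of -0.28 over 6 members, with Mesp2 at -0.64 and Tcf15 at -0.59, and of -0.41 in Nascent mesoderm. Its members Foxc2 (-0.41) and Dll1 (-0.15) were lower as well, although Foxc2 was at 0.25 in thinned cells. These 2 lists stood apart from random lists. The paraxial list was at -0.08 with totals without mitochondrial and ribosomal protein genes, at -0.07 with no filter beyond 1 UMI and at -0.14 with equal weights, all closer to 0 than the lower end of the middle 95% of random lists (-0.20).

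Genes of the extraembryonic mesoderm, the tissue where Hand1 is best known, had a median of -0.41 with 5 of 14 members above 0. Besides Hand1 and Acta2, Pmp22 (-1.47) and Foxf1 (-0.96) were the lowest. The direction of this list over all mesoderm depended on the setting. Its median was 0.11 without the Mesenchyme class of 22 and 83 cells, and -0.02 in cells of 20000 to 40000 UMIs. It was -0.07 with equal weights for the classes and -0.004 at a mean of 50 CPM or more. By class, the list was at -0.16 in Mixed mesoderm and in Blood progenitors, standing apart from random lists on the low side in both. In Nascent mesoderm alone 7 of 12 members were above 0 and the median was 0.21, apart on the high side. The smooth muscle and actin list was at -0.49 with 1 of 8 members above 0, with Tagln at -0.71, Myl9 at -0.71 and Cald1 at -0.51, and stood at -0.26 without Mesenchyme, where Tagln was at -0.07, and at -0.25 in cells of 20000 to 40000 UMIs. The list of the epithelial-mesenchymal transition was at -0.21 with 0 of 10 members above 0, including Zeb1 (-0.69), Cdh11 (-0.48), Snai1 (-0.33) and Itga5 (-0.30), and was at -0.08 in cells of 20000 to 40000 UMIs. With all 4 mesoderm classes, these 3 lists stood apart from random lists.

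The lateral plate and cardiac list did not stand apart in all mesoderm (median -0.11, 5 of 12 members above 0). Its members went both ways, with Bmp5 at 1.16 and Smarcd3, a subunit of the BAF chromatin remodelling complex, at 0.72 against Foxf1 at -0.96 and Tbx20 at -0.43. The BMP list had a median of -0.07 with 7 of 14 members above 0. Id2 (0.65), Id3 (0.42) and Msx2 (0.36), targets of BMP signalling, were above 0 beside Bmp5. The primitive streak list was at -0.19, with Eomes at -0.47, Cdx1 at -0.38, Mixl1 at -0.36 and Fst at 0.28. The list of allantois and posterior Hox genes was at -0.27 over 3 members, Cdx4 (-0.64), Cdx2 (-0.27) and Hoxb1 (0.25). The primitive streak list was at 0.19 at a mean of 50 CPM or more and at 0.00 with no filter beyond 1 UMI. Among cells of 20000 to 40000 UMIs, the lateral plate and cardiac list was at 0.01, the BMP list at 0.10, Tbx20 at -0.04 and Fst at 0.01. None of these 4 lists stood apart from random lists in all mesoderm.

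Targets of p53 were higher in the mesoderm of Hand1 CKO. All 6 measured members were above 0, with a median of 0.66 (percentile 100), which was 1.07 with equal weights for the classes. The median was 1.15 in thinned cells, where the members that pass the filter can differ. Single members hardly moved there, with Cdkn1a at 1.73, Phlda3 at 1.41, Ccng1 at 1.15 and Bax at 0.21. Cdkn1a was at 1.62, Phlda3 at 1.29, Ccng1 at 1.11 and the apoptosis gene Bax at 0.22. The median was 0.44 in Nascent mesoderm, with 4 of 6 members above 0 and an interval over members of -0.39 to 1.12. It was 1.25 in Mixed mesoderm (6 of 6 above 0) and 1.25 in Blood progenitors, where all 8 measured members were above 0. Outside the Mesp1 lineage it was 0.80 in ExE endoderm (4 of 6 members above 0), 0.20 in Epiblast and -0.22 in ExE ectoderm, and it was 0.13 in the Primitive Streak and 0.26 in the Anterior Primitive Streak. In each of these classes the list stood apart from random lists, in ExE ectoderm on the low side. The ExE endoderm class of Hand1 CKO may hold cells or RNA of the embryo proper. The primitive streak list was at 1.71 there and the visceral endoderm list at -0.94. A Mesp1 UMI was found in 20.8% of its thinned cells in Hand1 CKO and 4.83% in Ctrl. Its p53 value may therefore come in part from the Mesp1 lineage, which was not tested. Genes induced by dissociation had a median of -0.02 over 9 members in mesoderm, with Atf3 at -0.52, Btg2 at 0.40, Fos at -0.24 and Jun at -0.15, the last at 0.02 with equal weights for the classes. Their median was -0.37 in Blood progenitors, on the opposite side from the p53 list, but 0.24 in Mixed mesoderm, where 6 of 8 members were above 0, and in both the list stood apart from random lists. It also stood apart in ExE endoderm (0.58) and in ExE ectoderm (-0.22), on the same side as the p53 list.

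The lists of epiblast, visceral endoderm and definitive endoderm markers were also higher in the mesoderm of Hand1 CKO as a whole. In Blood progenitors the epiblast and ectoderm list was instead at -0.53 and the visceral endoderm list at -0.90, each with 1 of 5 members above 0. Over all mesoderm, the epiblast and ectoderm list had 7 of 8 members above 0 and a median of 0.57 (0.12 with equal weights for the classes), with Utf1 at 1.17, Pou5f1 at 0.79, Cdh1 at 0.68 and Pou3f1 at 0.65. All 7 measured members of the visceral endoderm list were above 0, with a median of 0.86 and with Rhox5 at 1.58, Apom at 1.09, the transport protein gene Ttr at 0.91 and Apoc2 at 0.86. Rhox5 was also among the leading genes of ExE ectoderm in both libraries. Own cluster 6, named visceral endoderm-like, held 1.59% of Nascent mesoderm in Hand1 CKO and 0.12% in Ctrl. Of Mixed mesoderm it held 1.63% and 0.46%. Such cells may raise this list in the mesoderm classes, and how far they do was not tested. In cells of 20000 to 40000 UMIs only, the epiblast list was at 0.08 and the visceral endoderm list at -0.21 (0.25 in thinned cells), with Apom at -0.14, Ttr at -0.38 and Apoc2 at -0.65. Without the 6% of cells with the highest doublet scores, Utf1 was at 2.38 and Rhox5 at 2.46. Haemoglobin UMIs outside Blood progenitors came to 6.26 CPM in Hand1 CKO and 1.92 CPM in Ctrl. The definitive endoderm list had 3 members, Trh, Cldn6 (1.06) and Krt19 (0.79), with a median of 1.06. Trh was also among the leading genes of Epiblast in Ctrl, and Sox17, Foxa2, Cer1 and Hhex did not pass the filter in mesoderm. The rise of this list thus need not be one of definitive endoderm. These 3 lists stood apart from random lists.

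The parietal endoderm list was lower, with 0 of 5 members above 0 and a median of -0.30, among them the basement membrane genes Col4a2 (-0.70), Col4a1 (-0.59), Lamb1 (-0.30) and Lama1 (-0.10), and was at -0.09 with no filter beyond 1 UMI. Col4a1 and Col4a2 overlap each other on opposite strands. Of the axial mesoderm list only Lhx1 and Gsc (-0.30) were measured in mesoderm, of the trophoblast list only Sct (0.72) and Cdx2, and of the germ cell list only Ifitm3 (0.46). The S phase list had a median of -0.11 and did not stand apart, with Mcm4 at -0.36, Dtl at -0.29, Mcm6 at -0.20 and Pcna at 0.21. G2/M genes had a small median of 0.11 that stood apart from random lists (percentile 99.7), with 8 of 14 members above 0. Top2a was at -0.37, Mki67 at -0.32, Cdc20 at 0.34 and Ccnb2 at 0.28. Outside mesoderm the G2/M list also stood apart on the high side in the Primitive Streak (0.17) and ExE ectoderm (0.12), but not in Epiblast (0.05). Glycolysis and hypoxia genes were at 0.02, with Slc2a1 at -0.50, Bnip3 at 0.30, Hk2 at -0.13 and Tpi1 at 0.09.

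**Figure D3:**
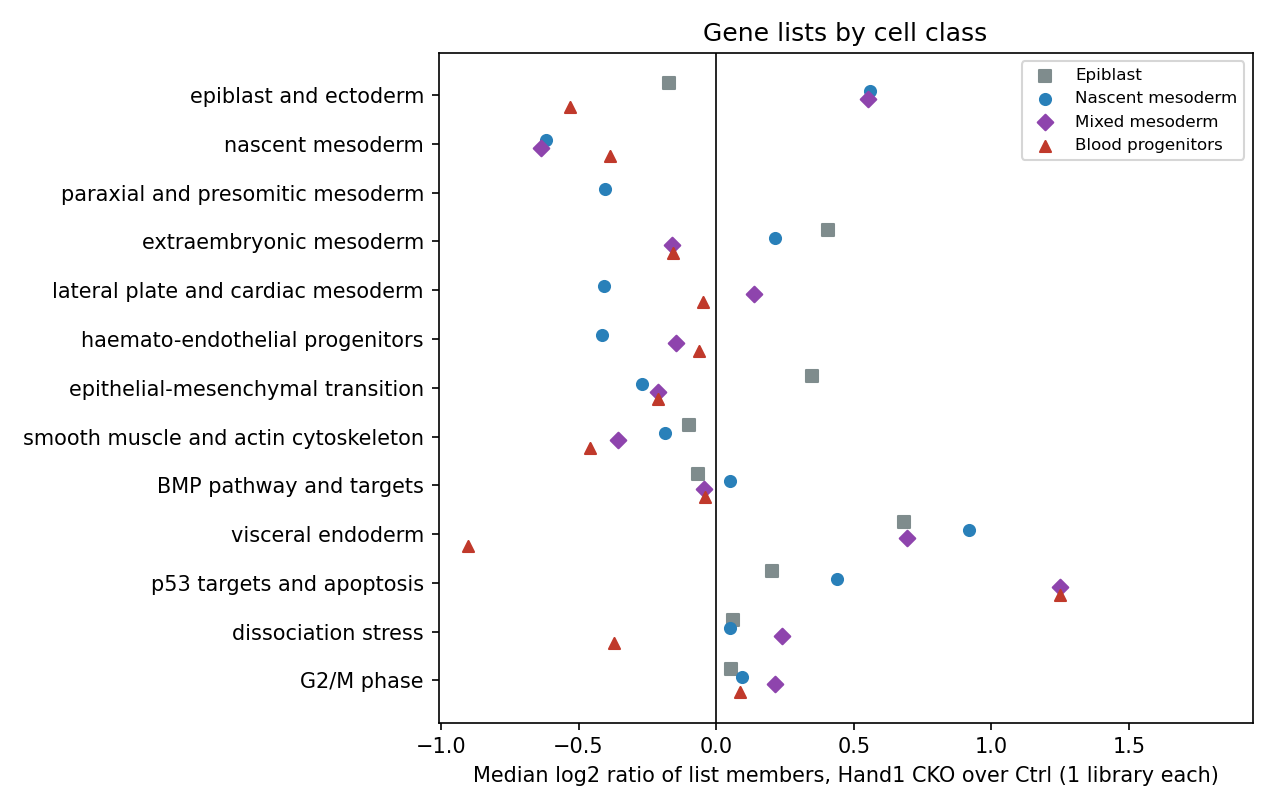
Median log2 ratio (Hand1 CKO over Ctrl) of the measured members of 13 gene lists in Epiblast, Nascent mesoderm, Mixed mesoderm and Blood progenitors, shown where 3 or more members were measured. The p53 list lies at 1.25 in Mixed mesoderm and in Blood progenitors and at 0.20 in Epiblast, and the nascent mesoderm list lies at -0.62 in Nascent mesoderm.

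Within Nascent mesoderm, the lowest log2 ratios were those of Mesp1 (-1.37), the cadherin gene Cdh20 (-1.30) and the semaphorin receptor gene Plxna4 (-1.13). The highest were those of Rpgrip1 (2.12), Rhox5 (1.75) and Mt2 (1.71). In cells of 20000 to 40000 UMIs Cdh20 was at -0.74, Plxna4 at -0.53, Rpgrip1 at 1.37, Rhox5 at 1.16 and Mt2 at 0.68. Of the own clusters, cluster 7, led by Lefty2 and Mesp1, held 46.3% of this class in Ctrl and 17.6% in Hand1 CKO. Cluster 5, led by Foxc2 and Aldh1a2, held 31.0% and 25.8%, and the shallow cluster 1 held 4.85% and 20.1%.

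Within Mixed mesoderm, Hoxb6 (-2.94, 2.61 CPM against 26.7 CPM), Tdo2 (-2.30) and Dlk1 (-2.28) were the lowest, and Gap43 (2.36), Spink1 (2.35) and Homer2 (2.15) were the highest. Spink1 was at 1.12 in cells of 20000 to 40000 UMIs. The lateral plate and cardiac list was at 0.14 in this class, with 9 of 13 members above 0 (percentile 97.8), and the extraembryonic mesoderm list at -0.16 (percentile 0.52). The own cluster with the largest part of this class differed between the 2 libraries. Cluster 4, led by Pmp22, Unc5c and Foxf1, held 74.2% of it in Ctrl and 27.5% in Hand1 CKO. Cluster 12, led by Bmp5, Kcnq5 and Hand2, held 41.2% of it in Hand1 CKO and 0.46% in Ctrl. Of the Mesenchyme cells, cluster 12 held all 22 in Hand1 CKO and cluster 4 held 81 of 83 in Ctrl. With 1 library per group, a cluster that comes almost wholly from 1 library may be that library and not a cell type.

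Within Blood progenitors, which fell mostly into own cluster 13 in both libraries (88.1% and 77.9%), the lowest log2 ratios were those of Rbp4 (-2.31), which encodes retinol-binding protein, of Hand1 (-1.69) and of the endothelial gene Ecscr (-1.68). The highest were those of 3 p53 targets, Cdkn1a (2.84, 72.6 CPM against 9.29 CPM), Phlda3 (2.62) and Ccng1 (2.52). The sums rest on 210 cells with 4437183 UMIs and 271 cells with 9043734 UMIs.

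Epiblast served as the comparison outside the Mesp1 lineage. The middle 95% of log2 ratios there ran from -0.29 to 0.31 over 7189 genes. The highest were Tex15 (1.44), the imprinted gene Phlda2 (1.32), Spink1 (1.29), Rpgrip1 (1.29) and Cdx2 (1.13). The lowest were Abcb7 (-0.57), Plac8 (-0.55), Platr10 (-0.54), the neurofilament gene Nefl (-0.52) and Fat3 (-0.51). Phlda2 was at 0.85 and Rpgrip1 at 0.71 in cells of 20000 to 40000 UMIs. Rpgrip1 and Spink1 were among the highest genes both in mesoderm and outside it. The visceral endoderm list was at 0.68 in Epiblast, with all 7 measured members above 0. The visceral endoderm-like own cluster 6 held 3.23% of this class in Hand1 CKO and 1.07% in Ctrl, and its part in that median was not tested. Own cluster 0 held 36.8% of this class in Hand1 CKO and 57.3% in Ctrl, and the shallow cluster 1 held 17.9% and 1.96%.

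Sex-linked genes differed between the libraries, as a different sex mix of the pooled embryos would give, but not alike in every class. Xist, which silences an X chromosome in female cells, was at 52.5 CPM over all cells of Hand1 CKO and 105.7 CPM over those of Ctrl. In mesoderm Xist had a log2 ratio of -0.63 and its antisense gene Tsix one of -0.32. Eif2s3y (0.44), Uty (0.44), Kdm5d (0.31) and Ddx3y (0.18), genes of the Y chromosome, were higher in Hand1 CKO. The sex-linked list had a median of 0.31 over 4 measured members. Xist was higher in Hand1 CKO in Mesenchyme (107 against 28.4 CPM), Def. endoderm (73.6 against 30.2 CPM) and PGC (74.8 against 54.8 CPM). In ExE ectoderm Xist was at 19.0 CPM against 114 CPM, and Eif2s3y at 28.9 CPM against 3.69 CPM. The classes may therefore hold different mixes of the pooled embryos, which limits comparisons of single classes and was not tested.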

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

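Of the tests below, those of a difference touching every cell and of Cre activity for the p53 targets, of a lost Mesp1 copy, and of Spink1 alone were chosen only after the result was seen.

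The next genes and lists were singled out because they lay on opposite sides of 0 in mesoderm and in Epiblast, outside the middle 95% of genes that passed the filter, or of random lists, in both. The difference itself was not tested. Mesp1 had a log2 ratio of -1.13 in mesoderm and 0.93 in Epiblast, a difference of -2.06. In thinned cells, 4.71% of Epiblast cells of Hand1 CKO and 2.04% of those of Ctrl had a Mesp1 UMI. Mesp1 was also higher in ExE endoderm of Hand1 CKO (44.5 against 26.5 CPM), but not in ExE ectoderm (21.9 against 23.5 CPM). The shallow own cluster 1 held 17.9% of Epiblast in Hand1 CKO and 1.96% in Ctrl. Whether Mesp1 was higher outside that cluster was not tested, so no opposite direction is claimed for it. Hbb-bh1 differed by -2.08 (-1.26 in mesoderm, 0.82 in Epiblast) and Dok4 by -1.99 (-1.59 and 0.39). Fgf3 differed by -1.51 (-1.16 and 0.35), Foxf1 by -1.47 (-0.96 and 0.51), Lhx1 by -1.46 (-0.69 and 0.77) and Lefty2 by -1.03 (-0.67 and 0.37). All 7 genes lay under the filter in Epiblast, at 0.894 CPM (Foxf1) to 5.86 CPM (Mesp1) in Ctrl. Set against the 500 genes nearest in level there, a comparison added after the values were seen, only Mesp1, Hbb-bh1 and Lhx1 stayed outside the middle 95% in Epiblast. Dok4, Fgf3, Foxf1 and Lefty2 lay within it, so no opposite direction is claimed for them. Nor is it for Hbb-bh1, since with equal weights for the classes it was at 1.06 in mesoderm, and its Epiblast levels (3.89 CPM against 1.77 CPM) went with those of haemoglobin outside Blood progenitors as a whole (6.26 CPM against 1.92 CPM). The extraembryonic mesoderm list differed by -0.82 (-0.41 and 0.41), but no opposite direction is claimed for it either, since in mesoderm it was at 0.11 without Mesenchyme, -0.02 in cells of 20000 to 40000 UMIs and -0.07 with equal weights. The list of the epithelial-mesenchymal transition differed by -0.56 (-0.21 in mesoderm, or -0.08 in cells of 20000 to 40000 UMIs, and 0.35 in Epiblast). The epiblast and ectoderm list differed by 0.74 (0.57 in mesoderm, or 0.08 in those cells, and -0.17 in Epiblast).

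A pair of signals lay outside the comparisons. Barcodes without a deposited annotation held 3.86% of all UMIs. Hand1 was at 33.0 CPM in the Visceral endoderm class of Hand1 CKO, from 24 UMIs in 6 of 22 cells, and had 0 UMIs in the 43 cells of Ctrl, where the 95% interval reaches 3.32 CPM. The related gene Hand2 went the same way, with 13 UMIs in 6 of the 22 cells (17.9 CPM) and 0 UMIs in Ctrl. The signal was thus not particular to Hand1, and its cause was not tested.

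The p53 targets were higher in the mesoderm of Hand1 CKO, with 6 of 6 members above 0, although Bax, Mdm2 and Pmaip1 lay within the middle 95% of genes. A difference between the libraries that touches every cell was argued against as the whole cause. The members' log2 ratios in mesoderm exceeded those in Epiblast by a median of 0.41 (95% interval of the median over members 0.10 to 1.12). Yet the list was at 0.80 in ExE endoderm and -0.22 in ExE ectoderm, with the dissociation list on the same side (0.58 and -0.22). In Blood progenitors the dissociation list was at -0.37, against 1.25 for the p53 list. A difference that reaches part of the cells beyond the Mesp1 lineage thus stays open. The value in ExE endoderm says little on this, since that class of Hand1 CKO may hold cells or RNA of the Mesp1 lineage. A Mesp1 UMI was found in 20.8% of its thinned cells in Hand1 CKO and 4.83% in Ctrl. The lower depth of Hand1 CKO was argued against too, since in cells of 20000 to 40000 UMIs the members kept a median part of 1.01 of their log2 ratio (0.53 to 2.18, the lower end only just above the bound of 0.5 set beforehand). Cre activity without regard to Hand1 stays open, since the members were higher by a median of 1.00 in Blood progenitors, where control Hand1 is low, than in Mixed mesoderm, but with an interval of -0.21 to 1.38, and no library with Cre alone was analysed here. Loss of Hand1 may also be the cause. It cannot be told apart from Cre activity, since Hand1 CKO is both the only library with Cre named and the only one meant to lose Hand1.

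Mesp1 was lower in Nascent mesoderm of Hand1 CKO. The lower depth was argued against, since in cells of 20000 to 40000 UMIs its log2 ratio was -1.15 (-1.21 to -1.10). Loss of 1 Mesp1 copy to an inserted Cre could lower it, and such a loss alone gives -1. The value was -1.37 (-1.41 to -1.34) over all cells of the class and nearer to -1 in cells of 20000 to 40000 UMIs. A copy lost in every cell would give -1 in other classes too. Mesp1 was at -1.41 in Mixed mesoderm and -1.24 in Blood progenitors. It was at -0.52 in Primitive Streak, -0.62 in PGC, -0.10 in ExE ectoderm, 0.73 in ExE endoderm and 0.93 in Epiblast. A lost copy as the only difference would not give these last values. The classes can differ in depth and in the cells they hold, and the intervals cover counting error only. How far such a loss accounts for the difference in Nascent mesoderm thus stays open. The labels do not say how Cre was placed under Mesp1. A smaller number of early cells within the class stays open, since within 4 bins of the cells by their UMIs of the other nascent mesoderm genes the mean was -1.08 (range -1.35 to -0.72), against -1.24 over all thinned cells. Loss of Hand1 itself was not tested apart from these.

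With p53 targets left out, among them Cdkn1a (1.62 in mesoderm, 0.50 in Epiblast), a set of 10 of the highest genes had counting intervals above 0 in both mesoderm and Epiblast (Amt, Fabp3, Mt1, Mt2, Phlda2, Rhox5, Rpgrip1, Spink1, Tex15 and Trh), although Trh, at 0.18 in Epiblast, lay within the middle 95% of genes there. The lower depth may account for part of this, since in mesoderm cells of 20000 to 40000 UMIs the median went from 1.47 to 0.75 and the members kept a median part of 0.58 (0.37 to 0.97), which stays open. RNA or cells of the extraembryonic endoderm were argued against for the excess in mesoderm. The share of 0.93% that 5 abundant markers gave (Apoa1, Apoc2, Apoe, Apom and Ttr, range 0.73% to 1.56%) accounted for a median part of 0.039 of that excess (interval of that median 0.016 to 0.19). Spink1 is the exception, since that share accounted for a part of 0.62 of its excess (0.48 to 1.03 over the markers), which stays open. The share was not computed for the excess in Epiblast, and no biological explanation was tested for this set.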

How the results depend on the processing

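Leaving out Mesenchyme, cells under 10000 UMIs, cells outside 20000 to 40000 UMIs or the 6% of cells with the highest doublet scores was chosen after seeing the data, and the other alternatives were planned. Over 15 alternatives and 168 results, 993 of 1382 values stayed within the counting interval of the reported value or, for lists, the interval of the median over members. Another 380 moved beyond it, and 9 turned the direction of a gene whose interval excluded 0 or of a list that stood apart. The alternative without called doublets was not run because the caller marked almost no cells. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Where a value is given below with no further word, the cause was not tested.

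The log2 ratio of Hand1 in mesoderm stayed below 0 under every alternative run. It was -1.14 with a pseudocount of 5 CPM, which shrinks low genes by construction, -1.01 in thinned cells, -1.04 without Mesenchyme, -1.06 in cells of 20000 to 40000 UMIs and -1.29 without the highest doublet scores. In thinned cells Foxc2 was at 0.25 and the sex-linked list at 0.48. With no filter beyond 1 UMI, more members entered, and the allantois and posterior Hox list was at -0.83 and the definitive endoderm list at 0.51. With equal weights for the classes, Hbb-bh1 was at 1.06, Lefty2 at 0.25, Jun at 0.0195, the haemato-endothelial list at -0.066, the p53 list at 1.07 (1.15 in thinned cells) and the definitive endoderm list at 0.71. The p53 median in thinned cells rests on the members that pass the filter there. The extraembryonic mesoderm list was at 0.11 without Mesenchyme, and the definitive endoderm list at 1.71 without the highest doublet scores. In cells of 20000 to 40000 UMIs, Apom was at -0.14, Ttr at -0.38, Apoc2 at -0.65 and the visceral endoderm list at -0.21.

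All mesoderm was 37.2% of Hand1 CKO cells without cells under 2000 UMIs. Without cells under 10000 UMIs, all mesoderm was 41.6% in Hand1 CKO and 31.9% in Ctrl, Nascent mesoderm 23.8% and 16.9%, Blood progenitors 3.23% and 5.10%, and in Hand1 CKO Mixed mesoderm 14.2% and Mesenchyme 0.49%. In cells of 20000 to 40000 UMIs, Nascent mesoderm was 19.5% and 16.7%, Mixed mesoderm 13.1% and 6.33%, and in Hand1 CKO all mesoderm 37.4%, Blood progenitors 4.22% and Mesenchyme 0.55%. Without extraembryonic endoderm and ectoderm, all mesoderm was 40.3% and 35.7%, Nascent mesoderm 24.2% and 18.5%, Mixed mesoderm 13.1% and 9.49%, and Blood progenitors 5.92% in Ctrl, as the smaller denominator gives. With own clusters all mesoderm was 26.8% and 28.4%, with 45.7% and 27.3% of cells in unnamed clusters. The depth of Hand1 CKO, with 27.2% of cells under 5000 UMIs, limits the shares of cells.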

Other observations

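No test of a cause is reported in this part, and the genes named in it, apart from Mesp1, Bmp5, Smarcd3, Foxf1, Ttr and Pou5f1, were chosen after their values were seen.

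In the Primitive Streak class, the nascent mesoderm and paraxial lists were higher in Hand1 CKO, while their medians over all mesoderm were below 0. The haemato-endothelial list was at 0.14 over 3 members in this class and did not stand apart from random lists. Of the nascent mesoderm list 7 of 8 members were above 0, with a median of 0.48, among them Rspo3 (0.61) and Tbx6 (0.81), while Mesp1 was at -0.52. All 4 measured members of the paraxial and presomitic list were above 0, with a median of 0.76, including the Notch ligand gene Dll3 (0.86) and Hes7 (0.71). The glycolysis and hypoxia list had 0 of 9 members above 0 and a median of -0.22, with Slc2a3, a glucose transporter gene, at -0.59. The class was shallower in Hand1 CKO (median 6101 UMIs against 24873.5), and own cluster 1 held 34.8% of it there and 5.04% in Ctrl, while cluster 0 held 11.1% and 31.9%.

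In ExE endoderm all 12 members of the visceral endoderm list were lower in Hand1 CKO, with a median of -0.94, among them Ttr (2785 CPM against 6283 CPM) and the endocytic receptor gene Cubn (-1.38). Some lists of the embryo proper were higher there, with a median of 1.71 over the 7 members of the primitive streak list, 1.29 over 6 members of the nascent mesoderm list and 0.94 over 10 members of the epiblast list. Others were not, with -0.18 for the lateral plate and cardiac list (1 of 5 members above 0) and -0.14 for definitive endoderm (3 of 6). The mesoderm transcription factor gene T had a log2 ratio of 2.14 and Pou5f1 at 162 CPM against 36.0 CPM. The p53 list was at 0.80 with 4 of 6 members above 0, and the dissociation list at 0.58 with 7 of 8 members above 0. Median depths were near each other, 11784 and 11307 UMIs. In ExE ectoderm the primitive streak list was at 1.12 over 5 members, the trophoblast list at 0.05 over 8 members, the p53 list at -0.22 with 2 of 6 members above 0, and the dissociation list at -0.22 with 4 of 10 members above 0.

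Within Mixed mesoderm, Hand2, the closest relative of Hand1, was at 35.0 CPM (32.6 to 37.6) in Hand1 CKO and 20.8 CPM (18.6 to 23.3) in Ctrl. The rise was not particular to this class. In Epiblast Hand2 had 35 UMIs in Hand1 CKO and 6 in Ctrl, and in the Primitive Streak 39 and 0. It was at 6.24 CPM against 0.82 CPM in ExE endoderm, but at 1.13 CPM against 2.99 CPM in Blood progenitors. Within Mixed mesoderm, beside Hand2, Bmp5 had a log2 ratio of 1.77, the atrial myosin light chain gene Myl4 one of 1.39 and Smarcd3 one of 1.20, against -1.09 for Foxf1 and -0.73 for Isl1. Of the allantois and posterior Hox list 1 of 4 members was above 0, with a median of -0.98. The own cluster with the largest part of this class was cluster 12 in Hand1 CKO (41.2%) and cluster 4 in Ctrl (74.2%).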
